A study of Homo sapiens with 4 samples.

How the data were processed

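Identical nylon cDNA filters were analysed, 1 for each of 4 groups of RNA from primary human umbilical vein endothelial cells. Control cells had received the vehicle, a balanced salt solution, and treated cells had received insulin at 100 µM for 2 h. Per the series' design text, ribosomes were then held on their mRNA with cycloheximide, cytoplasmic extracts were separated on sucrose gradients, and RNA was taken from the monosome fractions, where mRNA carries a single ribosome, and from the polysome fractions, where it carries several. Radiolabelled cDNA, made from this RNA with oligo-dT primers, was hybridised to Research Genetics filters of named human genes, and spots were read from phosphorimaging screens with the Pathways 3 software. Groups were taken from the sample titles, since other labels conflict with them. The source name of all 4 samples says that cells received vehicle, the descriptions of 3 samples name the control monosome fraction, and those 3 descriptions speak of histamine where the titles speak of insulin. A wrong title would turn or exchange the ratios given here.

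The deposited values are spot signals on a linear scale, above 0 for all 4132 probes on every filter. Per the series' design text, the authors divided each signal by the average signal of its filter. The deposited columns instead have a median of exactly 1 each and means of 4.70 (control monosome), 4.84 (control polysome), 5.19 (insulin monosome) and 4.77 (insulin polysome), so the signals are relative to each filter's median spot. Each value was therefore divided by its filter's mean, as the design text defines the measure, and the deposited scale was kept as an alternative. Whether a background was subtracted is not given in the sources used here. The authors' screen for spots with a signal over background above 1.1, per the design text, was not applied here, because the table used carries no background, so all probes entered the analysis.

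The translation state was the polysome signal over the monosome signal of a probe, and the translation index was the translation state in insulin cells over that in control cells, both as the design text defines them. Probes at 2.5 or above, or at 0.4 or below, were counted, which are the limits the design text gives. The same limits were applied to the ratio of insulin to control within each fraction. Each group held 1 filter, so nothing was tested between groups, no p-value was computed, and ratios carry no replicate error. In place of replicates, the spread of the translation index across probes was set beside that of other contrasts of the same 4 filters, and different probes of 1 gene were compared with 10000 sets of random pairs of probes matched on mean signal. The number of arrays limits the precision, and genes are not replicates.

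Gene names came from GEO's annotation of the filter, which can be old, and symbols were updated by gene number through the RefSeq gene table of assembly GRCh38.p14, used for names alone. Of the 4132 probes, 1582 had 1 gene symbol, 52 had several and 2498 were unnamed here. The gene number was found for 1580 of the 1582. Probes with several symbols named no gene, probes of 1 gene were averaged on the log2 scale, Y-linked genes and XIST were left out, and 1530 genes were measured. Before the data were examined, the rule for naming genes was fixed. It took genes with a mean log2 signal above the median of all genes, which left 765. Among these it named the 12 highest and 12 lowest translation indices past the limits, the 10 highest and 10 lowest mean translation states on the same side of 1 in both conditions, and the 5 highest and 5 lowest ratios of insulin to control in each fraction. It added up to 4 members of each gene list with the largest translation index in either direction, and the 4 brightest members of the ribosomal protein, translation factor and insulin signalling lists. Genes named outside this rule are said to be so.

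The same plan fixed 21 gene lists. They cover ribosomal proteins, translation factors, insulin signalling (with PI3K and mTOR), glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, endothelial genes, adhesion molecules and inflammatory mediators, immediate early genes, cytoskeleton, extracellular matrix, proteasome and ubiquitin, chaperones, cell cycle and DNA replication, apoptosis, antigen presentation and interferon, and markers of leukocytes, smooth muscle and fibroblasts, epithelium, erythroid cells and platelets, and other tissues. A list with at least 5 measured genes was described by the percentile of its median among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. A list was said to stand apart at a percentile of 2.5 or below or of 97.5 or above. This describes these filters and is not a test across samples.

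The alternatives were division by the filter median, quantile normalization, loess normalization of each filter against the mean of the 4 with a span of 0.4, removal of the dimmest 25% or 50% of probes, addition of 0.1 of the filter mean to each signal, subtraction of the filter's 1st percentile as a stand-in for background, limits of 4 and 0.25, and the brightest probe of each gene in place of the mean of its probes. Division by the filter mean without the brightest 1% of probes was added after the data were seen. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The counting was tested on simulated filters with 4132 probes and normal noise with an SD of 0.287 (log2) per filter at all signal levels. This SD was the observed robust SD of the log2 index divided by 2, so the simulation takes that whole spread as error. Of 67 probes given a 2.5-fold translation index, 46.3% were counted as past the limits, of 67 given a 4-fold index 86.6%, and of 66 given an 8-fold index 100%. Of 3932 probes with no simulated difference, 99 were counted. These shares hold for the assumed noise and are not measured error rates of the filters.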

Results

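The data were spot signals from 4 cDNA filters hybridised with RNA from monosomes and polysomes of control and insulin-treated human umbilical vein endothelial cells, the primary cells that line the umbilical vein. There was 1 filter in each of the control monosome, control polysome, insulin monosome and insulin polysome groups, as the sample titles give them, and other labels conflict with these titles. Each filter gave a signal for 4132 probes. The brightest 1% of probes, 42 on each filter, carried 43.5% of the signal on the control monosome filter, 43.8% on the control polysome filter, 44.6% on the insulin monosome filter and 42.3% on the insulin polysome filter. Between 75% and 80.2% of the probes lay within 0.5 to 2 times their filter's median. With no replicate of any group, no difference was tested, and each ratio compares single filters.

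The translation index asks which mRNAs shifted between monosomes and polysomes with insulin. Among the 765 genes of the brighter 50%, to which all rankings of genes here are limited, it was highest for GCKR, the regulatory protein of glucokinase, at 9.46, with a polysome to monosome ratio of 0.650 in control cells and 6.16 in insulin cells. CSF1R, the receptor for macrophage colony-stimulating factor, followed at 8.44 (0.309 in control and 2.61 in insulin cells). The index was 8.01 for MMP15, a membrane-bound matrix metalloproteinase, and 7.46 for ESR1, the oestrogen receptor alpha. LAGE3, a subunit of a complex that modifies transfer RNA, had an index of 6.57, and AIF1, a calcium-binding protein of macrophages, one of 5.73. DMWD, a WD repeat protein, stood at 4.93. The transcription factor JUNB stood at 4.37, with a ratio of 0.588 in control and 2.57 in insulin cells. ADAR, the adenosine deaminase that edits double-stranded RNA, stood at 4.36, with ratios of 0.584 and 2.55. The last of the 12 highest were the transcription factor SP2 at 4.01, the Golgi protein GOLGA4 at 4.00 and DDX12P at 3.69. DDX12P is a pseudogene of a helicase family, so its signal may belong to a related gene. Whether the other spots named here report mRNA of those genes in endothelial cells was not tested.

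Among the same genes the lowest index was that of TOMM40L, a relative of the import channel of the mitochondrial outer membrane, at 0.0618. Its ratio was 13.4 in control and 0.825 in insulin cells, and its control polysome signal was 10.2 times the geometric mean of its 3 other filters. NPTX2, a secreted pentraxin, had an index of 0.176. ONECUT1, a hepatic transcription factor, had one of 0.180 and NDUFA5, a subunit of respiratory complex I, one of 0.186, with ratios of 1.22 in control and 0.228 in insulin cells for NDUFA5. ZNF35, a zinc finger protein, stood at 0.223 and ISCU, the scaffold for iron-sulphur cluster assembly, at 0.234. PLA2G7, which degrades platelet-activating factor, stood at 0.246. CADPS, which primes vesicles for secretion, stood at 0.25, the phosphatase relative MTMR11 at 0.251 and the F-box protein FBXW2 at 0.258. BDKRB2, the bradykinin receptor of the endothelium, stood at 0.260 and S100B, a calcium-binding protein, at 0.281. For ONECUT1, NDUFA5, ISCU, PLA2G7 and S100B a single filter stood out while the 3 others lay within 1.5-fold of each other. That filter was the insulin monosome filter, except for S100B, where it was the control polysome filter. Among the 12 highest this held for LAGE3 and DDX12P. TOMM40L had signals of 0.099 (control monosome), 0.163 (insulin monosome) and 0.134 (insulin polysome) filter means, each below its filter's median. For ONECUT1, PLA2G7 and S100B the 3 other filters also lay below their medians. These genes rank as brighter by mean signal only through the high filter that sets their index. No background is given, so signals near background stay open as a source of their ratios.

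**Figure D1:**
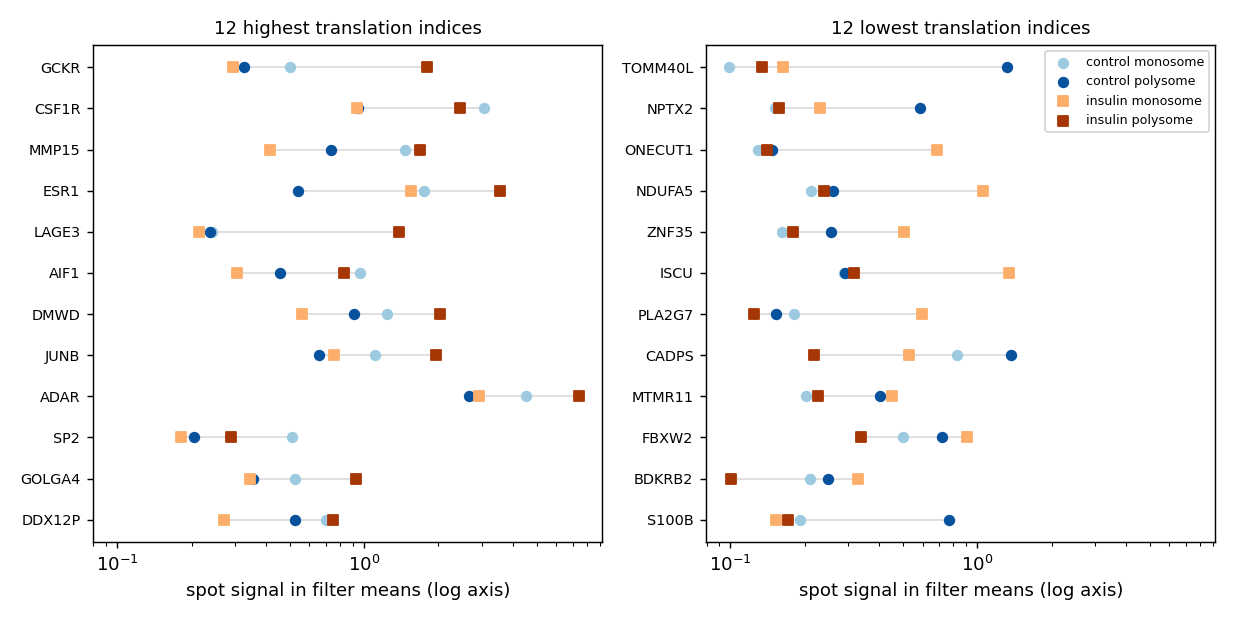
Spot signals of the 12 named genes with the highest (left) and the 12 with the lowest (right) translation index, in filter means on a log axis, 1 point per filter, with circles for control cells and squares for insulin cells. Polysome and monosome signals moved in opposite directions between control and insulin cells for all 12 genes on the left and for 9 of the 12 on the right. Choosing genes by an extreme index favours such opposed movement by itself.

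Over all 4132 probes, 133 had an index of 2.5 or above and 87 one of 0.4 or below, 220 in all or 5.32%. Of the 1530 genes, 42 were at or above the upper limit and 30 at or below the lower. The share of higher probes among those counted depended on the scaling. It was 60.5% as defined, against 42.4% after division by the filter median, 48.6% after quantile normalization and 47.0% after loess normalization. The median log2 index was 0.11 as defined and -0.05 after division by the filter median, so the side of 1 on which an index near 1 lies depends on the scaling. In 195 of the 220 probes the polysome and monosome signals moved in opposite directions between control and insulin cells. The index is the polysome change over the monosome change, so choosing probes by a large index favours opposed movement under spot error alone. How many would be opposed without any change was not computed, so this count is no evidence of a shift. The count was 93 with 0.1 of the filter mean added to each signal and 1087 with the 1st percentile subtracted as background.

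How large an index these filters give by spot error alone can be judged only from the filters themselves. The mean log2 ratio of insulin to control over both fractions rests on the same 4 spots with the same weights as the log2 index divided by 2. Its robust SD across probes was 0.29 (0.291), and that of the log2 index divided by 2 was 0.29 (0.287). The ratio of the 2 spreads was 0.987, with a bootstrap interval over probes of 0.941 to 1.04. The contrast of insulin with control would also hold any change in mRNA amount with insulin, so its spread is not spot error alone. The mean log2 polysome to monosome ratio over both conditions had a robust SD of 0.38. Counted about the median at limits of the same size, 209 probes lay past them on the index, 172 on the contrast of insulin with control and 558 on the contrast of polysomes with monosomes. For 36 genes with more than 1 probe, the log2 index of different probes correlated across genes with r of -0.169, at the 17.3 percentile of random pairs. The bootstrap interval of this r was wide, -0.546 to 0.180. The mean log2 polysome to monosome ratio correlated with r of 0.419, at the 97.6 percentile. Within single conditions r was 0.314 in control cells, at the 93.5 percentile, and 0.177 in insulin cells, at the 82.6 percentile.

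Immediate early genes, which respond within minutes to growth factors, were low on the translation index as a list. The median of their 17 measured members was 0.802, at the 0.89 percentile of random lists, and 3 members lay above the median of all genes. CCN1, a secreted matrix protein, stood at 0.568, IER2 at 0.524 and the transcription factor JUN at 0.644. JUNB was the exception at 4.37, and DUSP4, a phosphatase of MAP kinases, at 1.5 and FOSL1, a partner of Jun proteins, at 1.41 were the other members above the gene median (both named after their values were seen). On the polysome filters the list's median ratio of insulin to control was 0.880, at the 3.22 percentile, and on the monosome filters it was 0.978, at the 59.5 percentile. The percentile of the index lay between 0.55 and 2.19 under all alternatives, though those that only rescale whole filters cannot change it. It was 2.94 without FOSL2 and 2.61 without KLF6.

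Genes of insulin, PI3K and mTOR signalling had a median index of 1.22 over 16 members, at the 88.2 percentile, and 13 members lay above the gene median. TSC2, which restrains mTOR, stood at 1.88, the transcription factor FOXO1 at 1.59, GRB14, an adaptor that binds the insulin receptor, at 1.59 and the kinase RPS6KA1 at 1.42. The bright members PIK3CD, a catalytic subunit of PI3K, and SHC1, an adaptor of receptor tyrosine kinases, stood at 1.10 and 1.15. PRKAG1, a subunit of AMP-activated kinase, was past the upper limit at 2.53 (named after its value was seen). The list came to stand apart at 97.9 with loess normalization and at 98.7 without the dimmest 25% of probes. Translation factors had a median index of 1.13 over 7 members, at the 61.8 percentile, but stood apart at 97.8 with the brightest probe of each gene. EIF4G1, the scaffold of the cap-binding complex, stood at 1.91, BTF3 at 1.90, the poly(A)-binding protein PABPC4 at 1.58 and the release factor ETF1 at 0.693, while EIF1 stood at 1.13 and EIF2B5 at 0.948. RPL31 was the only ribosomal protein measured, with an index of 0.730.

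Apoptosis genes had a median index of 1.34 over 15 members, at the 95.9 percentile, and 11 members lay above the gene median. FADD, the adaptor of death receptors, stood at 2.11, CFLAR, which blocks caspase activation, at 1.89, and the caspases CASP4 and CASP10 at 1.80 and 1.62. Among oxidative phosphorylation genes the median of 5 members was 0.742, at the 4.92 percentile. NDUFA5 stood at 0.186 as given above, NDUFA13 at 0.693, the succinate dehydrogenase subunit SDHD at 0.742 and cytochrome c (CYCS) at 1.39. Proteasome and ubiquitin genes had a median of 0.917 over 18 members, at the 5.26 percentile, with the ubiquitin protease USP14 at 0.580, the conjugating enzyme UBE2A at 0.729, USP4 at 0.737 and USP8 at 1.45. Cytoskeletal genes had a median of 1.23 over 13 members, at the 89.7 percentile, with ARPC2, a subunit of the actin-nucleating Arp complex, at 2.20 and the myosin heavy chain MYH10 at 2.01.

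Endothelial genes had a median index of 1.19 over 11 members, at the 83.2 percentile. LMO2, a transcriptional cofactor of endothelium and blood, stood at 1.91, the growth factor ANGPT2 at 1.43, the junction protein CDH5 at 0.720 and the endothelin-converting enzyme ECE1 at 0.587. Adhesion molecules and inflammatory mediators had a median of 1.09 over 9 members, at the 54.0 percentile, with the integrin ITGAV at 1.99, the chemokine CXCL10 at 0.451 and the superoxide dismutase SOD2 at 0.723. Extracellular matrix genes had a median of 1.01 over 10 members, at the 41.4 percentile, with LUM at 1.69 and the collagen-modifying enzyme PLOD2 at 0.586. Cholesterol and fatty acid synthesis genes had a median of 1.14 over 10 members, at the 68.2 percentile, with EBP at 1.98 and ACAT2 at 1.90. Cell cycle and DNA replication genes had a median of 1.01 over 21 members, at the 27.7 percentile, with the helicase subunit MCM3 at 1.62, the kinase CDC7 at 0.753 and the cyclin CCNH at 0.683. Chaperones had a median of 1.15 over 9 members, at the 71.1 percentile, with DNAJB1 at 0.780 and PPIC at 1.23. Antigen presentation and interferon genes had a median of 1.04 over 7 members, at the 40.4 percentile, with the proteasome activator PSME1 at 1.25 and IRF2 at 0.840.

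Of the lists for cells other than endothelium, only the leukocyte list held members past the limits of the translation index. Leukocyte markers had a median of 1.08 over 9 members, at the 60.6 percentile, with CSF1R at 8.44 and AIF1 at 5.73, as above, and TYROBP, an adaptor of myeloid receptors, at 0.392. Smooth muscle and fibroblast markers had a median of 1.02 over 10 members, at the 37.6 percentile, with COL6A2 at 0.869 and CALD1 at 0.962. Epithelial markers had a median of 1.16 over 6 members, at the 67.2 percentile, with the tight junction protein CLDN4 at 0.523 and the keratin KRT4 at 1.63. Genes restricted to liver, brain, pancreas, pituitary and skeletal muscle had a median of 1.04 over 5 members, at the 41.3 percentile, with ITIH4 at 0.707 and TNNT3 at 0.626. Of the erythroid and platelet markers 3 were measured, ANK1 at 0.775, KLF1 at 0.984 and RHAG (outside the naming rule) at 0.864.

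**Figure D2:**
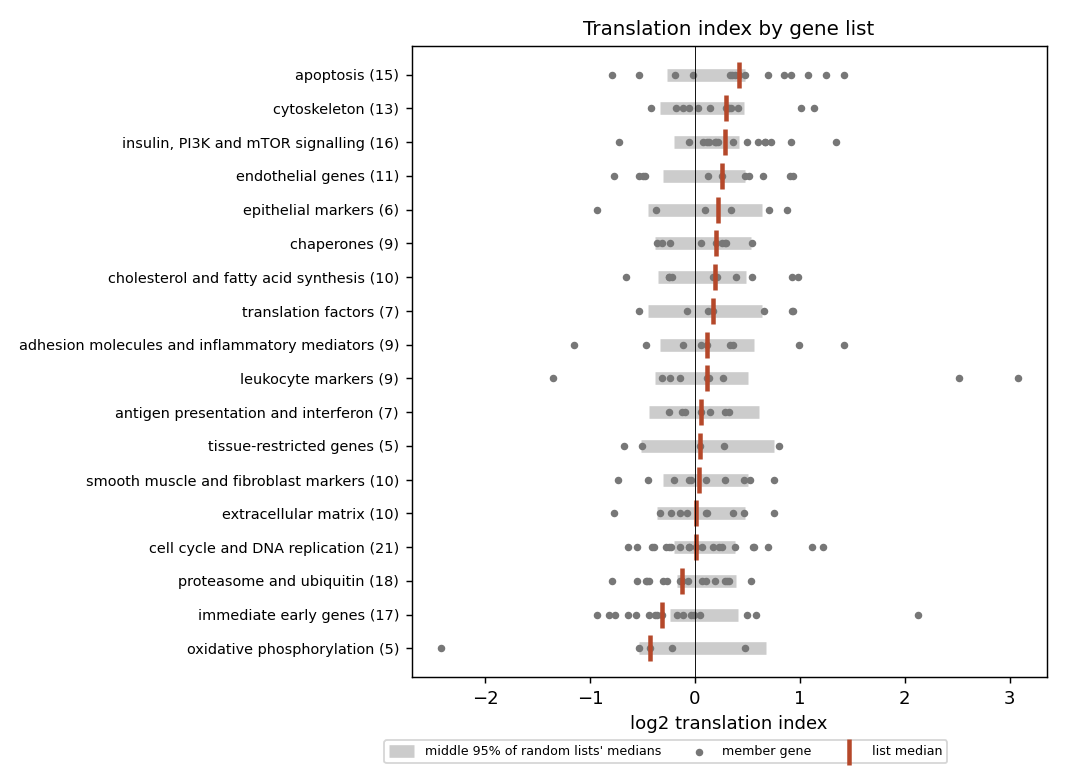
Log2 translation index of the measured members (points) of the 18 gene lists with at least 5 members, with each list's median (red bar) and the middle 95% of the medians of random lists matched on signal (grey bar), and the number of members in parentheses. The median of the immediate early genes lies below its grey bar while JUNB lies at 2.13, and the other list medians lie within theirs.

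Over the 18 lists and 4 measures, 72 medians were compared and 4 stood apart. When gene names were exchanged among genes of like signal, the median number standing apart was 3, and 47.1% of 1000 exchanges gave 4 or more.

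The polysome to monosome ratio asks which mRNAs were held in polysomes in each condition. By its mean over both conditions, among genes of the brighter 50% on the same side of 1 in both, it was highest for ELN, the elastin precursor, at 2.06 in control and 4.90 in insulin cells, and for SRGN, the proteoglycan of secretory granules, at 2.50 and 3.56. RND3 stood at 3.40 and 2.50, BASP1, a membrane-bound signalling protein, at 2.44 and 3.37, and PTMA, a nuclear acidic protein, at 2.52 and 3.17. ARPC2 stood at 1.88 and 4.13, the splicing factor SRSF3 at 2.09 and 3.57, the nuclear receptor NR0B2 at 2.29 and 3.2 and the lactonase PON2 at 2.18 and 3.05. Cytoplasmic actin (ACTB), measured by 2 probes, stood at 2.47 and 2.74.

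By the same mean and among the same genes, the ratio was lowest for SYNPO, an actin-associated protein, at 0.123 in control and 0.205 in insulin cells. SMARCD2, a subunit of a chromatin remodelling complex, stood at 0.219 and 0.294, and the stress-activated kinase MAPK8 at 0.262 and 0.272. The ribosomal protein RPL31 stood at 0.430 and 0.313 and the selenoprotein SELENOW at 0.431 and 0.386. PLA2G7 stood at 0.847 and 0.209, the ubiquitin ligase MARCHF6 at 0.354 and 0.587, TYROBP at 0.747 and 0.293 and the noradrenaline transporter SLC6A2 at 0.340 and 0.670. PLA2G7 ranks as brighter only through its insulin monosome signal, as given above. SVIL-AS1, at 0.685 and 0.279, is an antisense gene whose signal may belong to the gene on the other strand.

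**Figure D3:**
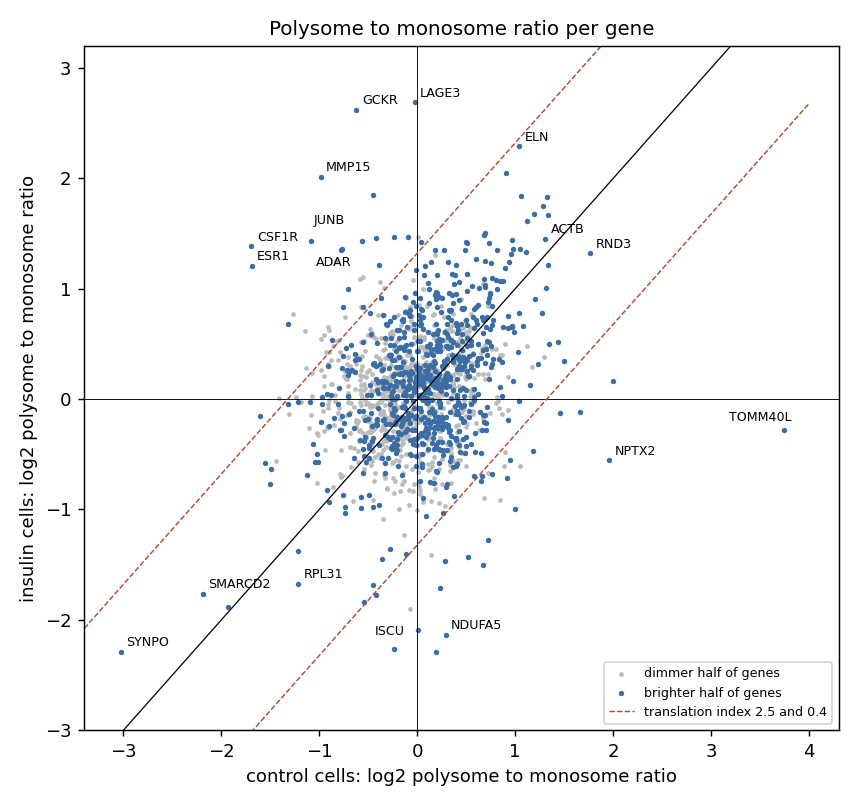
Log2 polysome to monosome ratio of each measured gene in control cells (x axis) and insulin cells (y axis), with genes in the brighter 50% in blue, equality as a solid line and the translation index limits of 2.5 and 0.4 as dashed lines. ELN, RND3 and ACTB lie high and SYNPO, SMARCD2 and RPL31 low in both conditions, while GCKR, CSF1R and TOMM40L lie far from the solid line.

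In control cells 61 probes had a ratio of 2.5 or above and 63 one of 0.4 or below, and in insulin cells 129 and 70. Ratios of 2.5 or above in both conditions were found for 25 probes, where independent lists would share 1.90, and ratios of 0.4 or below in both for 19, where independent lists would share 1.07. All of these lay in the brighter 50% of probes, within which independent lists would share 3.51 and 1.71. Across all probes the log2 ratios of control and insulin cells correlated with r of 0.331. The r was 0.0113 for the dimmest 25% of probes and 0.584 between the 90 and 99 signal percentiles. In control cells 49.2% of the counted probes were higher, against 56.6% after division by the filter median, 32.8% after quantile and 25.7% after loess normalization. In insulin cells 64.8% were higher, against 51.7% after division by the filter median, 44.7% after quantile and 41.8% after loess normalization.

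Cytoskeletal genes stood apart on the mean polysome to monosome ratio, with a median of 1.29 at the 98.3 percentile, and 9 of the 13 members lay above the gene median. ARPC2 and ACTB, given above, were past the upper limit on the mean of both conditions, RDX, which links actin to the membrane, had a mean ratio of 1.56 and CALD1, an actin-binding regulator, one of 0.919. Apoptosis genes stood apart with a median of 1.21 at the 97.7 percentile, with FADD at 1.76 and CYCS at 1.68. Both calls depended on the processing. With loess normalization the percentile was 86.2 for the cytoskeletal and 62.4 for the apoptosis list, and with quantile normalization 85.8 and 67.3. The cytoskeletal list stood apart under 4 of 10 settings, as defined included, while the apoptosis list did so under 5 of 10. Among those settings, division by the filter median and by the mean without the brightest 1% only rescale whole filters. They cannot change a percentile and so add nothing to the call as defined.

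The ratio of insulin to control within the polysome fraction shows which side of the index moved. Among genes of the brighter 50% it was highest for ESR1 at 6.59, LAGE3 at 5.83 and GCKR at 5.56, followed by RTN3, a protein of the tubular endoplasmic reticulum, at 3.19 and JUNB at 2.98. It was lowest for TOMM40L at 0.102, CADPS at 0.160, S100B at 0.224, NPTX2 at 0.269 and the phosphatidylinositol transfer protein PITPNM1 at 0.302. TOMM40L and S100B rank as brighter only through their control polysome signal, as given above. Over all probes 25 were at 2.5 or above and 29 at 0.4 or below. Apoptosis genes stood apart, with a median ratio of 1.26 at the 99.4 percentile and 9 of 15 members above the gene median. CFLAR stood at 1.67, CASP4 at 1.63, CASP10 at 1.42 and FADD at 1.26. The list's percentile lay between 98.4 and 99.6 under all settings, though those that only rescale whole filters cannot change it.

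Within the monosome fraction the ratio of insulin to control was, among genes of the brighter 50%, highest for ONECUT1 at 5.34, the keratin KRT20 at 5.26, NDUFA5 at 4.96, ISCU at 4.66 and TYROBP at 3.56. Among these genes it was lowest for MMP15 at 0.284, CSF1R at 0.307, AIF1 at 0.317, SP2 at 0.354 and DDX12P at 0.388. KRT20 had a signal of 0.756 filter means on the insulin monosome filter and of 0.105 to 0.236 on the others. ONECUT1 ranks as brighter only through its insulin monosome signal, as given above. Over all probes, unnamed ones included, the ratio ranged from 0.136 to 16.3, and 37 were at 2.5 or above and 23 at 0.4 or below. Higher probes made up 61.7% of these, against 81.7% after division by the filter median, 76.7% after loess normalization and 46.6% with the 1st percentile subtracted. No list stood apart on this ratio as defined. Oxidative phosphorylation genes had a median of 1.28 over 5 members, at the 96.5 percentile, and came to stand apart at 98.3 with quantile, 98.2 with loess normalization and 97.8 with the 1st percentile subtracted. Of the 220 probes past the limits of the translation index, 121 owed the larger part to the monosome filters and 99 to the polysome filters.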

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

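The tests of spot error and of dim spots given here were chosen after the result was seen. For 4 probes the polysome to monosome ratio lay past opposite limits in control and insulin cells, and the difference was not tested, since each condition has 1 filter per fraction. The ratio of CSF1R, the macrophage colony-stimulating factor receptor, was 0.309 in control and 2.61 in insulin cells, an index of 8.44. Unnamed probe 2773 had ratios of 0.171 and 4.63 and an index of 27.1, and unnamed probe 3761 ratios of 0.264 and 2.94 and an index of 11.1. Unnamed probe 3796 went the other way, with ratios of 2.63 and 0.203 and an index of 0.0771. All 4 lay in the brighter 50% of probes. Within these, independent lists would give 3.45 probes low in control and high in insulin cells, where 3 were found. They would give 1.74 of the other kind, where 1 was found. The ratios of control and insulin cells were not independent there, as they correlated with r of 0.413. Related ratios would give fewer probes past opposite limits, so these counts cannot be judged against independent lists.

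The 220 probes past the limits of the translation index are the pattern that would most need a follow-up, GCKR, CSF1R, JUNB and TOMM40L among them. Of these probes 134, or 60.9% (95% interval 54.3 to 67.1), lay in the brighter 50% by the median of the 4 filters, which a single high filter cannot set. This cannot decide on spots near the background. Between 75% and 80.2% of all probes lay within 0.5 to 2 times their filter's median, and no background is given. The brighter 50% need therefore not be clear of background. Dim spots stay open as a source, and 93 probes were left with 0.1 of the filter mean added. Error of single spots may account for much of the count, but it was not measured. The contrast of insulin with control over both fractions rests on the same spots. Doubled to the scale of the log2 index and taken about its median, it had 172 probes past the limits. The index about its median had 209, a ratio of 0.823. That contrast would also hold any change in mRNA amount with insulin or between preparations. The contrast thus cannot show how much of the count is error. It would bound spot error from above only if errors were alike and independent across the 4 filters, which was not tested. A single filter out of line and a shift with insulin cannot be told apart for the group, as in 46 of the 144 brighter probes (31.9%) the 3 other filters lay within 1.5-fold of each other, and that filter was the insulin monosome filter for 20. Ranking by mean signal favours such probes where the single filter is high, as it was for 31 of the 46. An effect of insulin on the translation of these mRNAs stays open and untested, since each condition was measured once.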

How the results depend on the processing

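Division by the filter mean without the brightest 1% of probes was chosen after the data were seen, and it moved no count by more than 1.5 times. No paired analysis of the translation index was possible because each group held 1 filter. The number of probes past the limits of the translation index, 220 as defined, was 144 without the dimmest 50% of probes, which leaves fewer probes to count, 93 with 0.1 of the filter mean added, 1087 with the 1st percentile subtracted and 58 at limits of 4 and 0.25. With 0.1 of the filter mean added, the counts were 66 for the control polysome to monosome ratio, 117 for the insulin one, 34 for insulin over control in polysomes and 27 in monosomes. With the 1st percentile subtracted they were 780, 868, 552 and 659, and at limits of 4 and 0.25 they were 20, 40, 16 and 13. These shifts follow from how each setting is made, since an added constant draws the ratios of dim spots to 1 and a subtracted one drives them apart. Of the list medians, 2 stood apart without the dimmest 50% of probes and 7 with the 1st percentile subtracted, against 4 as defined, and the cause was not tested. A further 9 list medians stood apart under 1 to 3 of the alternatives but not as defined. The 220 probes shared 173 with those counted after division by the filter median, 190 after quantile and 184 after loess normalization. At limits of 2.5 and 0.4, the 24 genes named for their translation index stayed past them under each alternative that measured them, except BDKRB2 with 0.1 of the filter mean added. Each of the 24 had 1 probe, so leaving out dim probes or taking the brightest probe could not change its index. They were also chosen as the most extreme, and rescaling whole filters moves all indices alike. Much of this stability was therefore fixed in advance. At limits of 4 and 0.25, 18 of the 24 were past them and BDKRB2, CADPS, DDX12P, FBXW2, MTMR11 and S100B were not. The ratio of the spread of the index to that of insulin against control lay between 0.987 and 1.02 under all settings run, and the correlation of the index between probes of 1 gene between -0.270 and -0.0541. The lack of a background value limits what dim spots show.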

Other observations

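The test of filters of 2 kinds, the comparison of the brightest spots and the ranking of members by the median of the filters were chosen after the result was seen. Glycolysis genes were too few for a percentile. All 4 measured members had a translation index above that of the median probe, 1.08, as 50% of all probes have by definition. With 4 members, this count shows no trend of the list. LDHA, lactate dehydrogenase, stood at 1.54, PFKL, the liver phosphofructokinase, at 2.16, PGD, of the pentose phosphate pathway, at 2.19 and PDK2, which inhibits pyruvate dehydrogenase, at 1.15. Among cell cycle genes the checkpoint kinase CHEK1 at 2.33 and the mitotic kinase AURKA at 2.17 had the highest indices, and in the apoptosis list CASP9, the initiator caspase of the mitochondrial pathway, stood at 2.67. TNFAIP1, of the inflammatory list, stood at 2.68. PFKL, PGD, PDK2, CHEK1, AURKA, CASP9 and TNFAIP1 lie in the dimmer 50% of genes and were chosen after their values were seen.

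The brightest spots differed little between filters, and not only between fractions. Of the 42 probes in the brightest 1%, 41 (97.6%) had a mean polysome to monosome ratio within 1.5-fold of 1, against 228 of 372 (61.3%) between the 90 and 99 percentiles. The robust SD of the contrast of insulin with control was 0.142 against 0.275 in these bins. That of the log2 index divided by 2 was 0.124 against 0.330. Those 42 include MALL, a lipid raft protein, at a mean ratio of 1.16, CALD1 at 0.919, the phosphatase INPP5J at 1.09 and FANCG, of the DNA repair pathway of Fanconi anaemia, at 1.02, all chosen after their values were seen except CALD1. These spots carry over 40% of the signal and so weigh most in the filter mean.

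Among the 372 probes between the 90 and 99 signal percentiles, those with higher polysome signals in insulin cells tended to have lower monosome signals, with r of -0.260 (bootstrap interval -0.396 to -0.131). This bin was singled out after the values were seen, since r was -0.0567 over all probes, -0.0976 between the 75 and 90 percentiles and 0.0836 in the brightest 1%, and a movement of mRNA between fractions with insulin is a hypothesis that was not tested. A few extreme probes are argued against by a Spearman rho of -0.220, and a scaling that follows signal by r of -0.249 (-0.385 to -0.121) after loess normalization. A sharper separation of the fractions in 1 of the gradients is argued against as well, since the log2 index was not related to the mean log2 polysome to monosome ratio, with r of 0.0179 (-0.076 to 0.114). Filters of 2 kinds, with control monosome and insulin polysome alike, cannot be told apart from a shift with insulin. Both pairs lay within 1.5-fold in 43 of the 144 brighter probes past the limits (29.9%), and filter lots are not given in the sources used here.

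For the low translation index of immediate early genes, a hypothesis is that their mRNAs may be less loaded on polysomes 2 h after insulin, which was not tested apart from the index itself. Members in the dimmer 50% of genes do not alone carry the low index. The 11 members in the brighter 50% had a median log2 index 0.45 below that of all genes (a difference of -0.4544), and 10 of them lay below it. Ranked by the median of the filters, 10 members were in the brighter 50%, with a difference of -0.33, and 9 lay below. The brighter 50% need not be clear of background, which is not given, so signals near background stay open. Chance among lists stays open, as 26.8% of 1000 exchanges of gene names within signal bins gave at least 1 of 18 lists a percentile as far out. The call also rests on single members, since the percentile reached 2.94 without FOSL2.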
